A study of Mus musculus with 12 samples.

How the data were processed

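Dorsal root ganglia of adult male C57BL/6J mice aged 9 to 10 weeks were profiled by RNA-seq in 12 libraries, 3 from naive mice and 3 each from 1, 3 and 7 days after spared nerve injury. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, amplified with a Nugen Ovation kit for an input of 500 pg and made into libraries with TruSeq Nano. The strandedness of the libraries is not stated in the labels, so reads of a gene and of an overlapping antisense gene cannot be told apart. Amplification from low input can add spread between libraries, and amplified reads without molecular identifiers are not independent molecules.

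Per the submitters' processing notes, bcl2fastq 2.17, STAR, HTSeq, edgeR and limma were used with the mm10 genome build, with no role or order stated for any of them. The other tool versions, the gene annotation and the counting options are not given in the sources used here. The deposited values were read as RPKM, that is reads per gene divided by gene length and by library size by the authors, although no unit is written in the files. This was inferred from the values, since within a gene they were whole multiples of what 1 read is worth, and the gene lengths this implied had a median ratio of 0.781 to exon lengths in GENCODE M21. The files name 24060 genes by symbol, of which 21597 were above 0 in at least 1 library. Among the symbols, 27 had been turned into dates, 4 of them in duplicated entries, and 22776 symbols (94.7%) were found in GENCODE M21, from which mm10 coordinates were taken.

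Whole reads were recovered from the steps between values for 19755 of the 21597 detected genes (91.5%), with a tolerance of 0.05 reads. Library sizes recovered this way ran from 13627000 to 17953000 reads, so 1 read in a gene of 1 kb was worth 0.0557 to 0.0734 RPKM. Genes with an RPKM of at least 1 in at least 3 libraries were kept, which left 14195 genes. Libraries were scaled with trimmed means of log ratios, computed without weights after trimming 30% of log ratios and 5% of average levels at each end. Values were then taken as log2(RPKM + 0.5), so fold changes are on that scale and understate the change of low genes.

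The design had foreseen counts and a count model. Since the files hold RPKM, limma 3.58.1 in R 4.3.3 was used in its place, with statmod 1.5.0. All 12 libraries entered a single model of 4 group means with 8 residual degrees of freedom, with a variance trend on expression level and robust moderation. Each day was compared with naive and the days with each other, and a test of all 4 groups together gave the genes that differed at any time. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The smallest p of an exact permutation test of 3 against 3 libraries is 0.1, so single genes were tested only in the model across all genes. Values per group are means with the SD of 3 libraries.

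Gene groups were tested with camera from limma, using a preset correlation of 0.01 between genes, and again with a correlation estimated for each list. The adjusted p was taken over the lists. The 31 lists covered injury-induced neuronal genes, nociceptor receptors and peptides, mechanoreceptors and proprioceptors, potassium channels, sodium and calcium channels, synaptic transmission and general neuron markers. Others covered macrophages, neutrophils, lymphocytes, antigen presentation, complement, cytokines and chemokines, the interferon response, satellite glia, myelinating and repair Schwann cells, fibroblasts and matrix, vessels, erythrocytes, muscle, adipocytes and central glia. The rest covered cholesterol synthesis, cell division, replication histones, immediate early genes, stress and chaperone genes, glucocorticoid and circadian genes, ribosomal proteins and the respiratory chain. Lists with fewer than 5 tested members were not tested. Numbers of genes given for a list count its tested members, and members below the expression filter were not assessed. Tested were 13 of 33 cytokines and chemokines, 15 of 24 cell division genes, 12 of 18 immediate early genes and 10 of 68 replication histones. Of the cell division genes, 8 had a naive mean of at least 1 RPKM. Some genes stand in more than 1 list, among them Csf1, Cacna2d1 and the C1q genes.

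The comparisons, the lists, the first set of other settings and the rule for named genes were fixed before the data were examined. For each comparison with naive the rule took the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 value above 2 and all 3 injured libraries on the same side of all 3 naive libraries. Predicted and unnamed genes were left out. Between days it took 5 of each, and it added up to 4 members per list with the smallest p, and always Atf3, Sprr1a, Gal, Npy, Gap43, Sox11, Csf1 and Scn10a. Some genes that the rule took are not reported here.

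That first set varied the scaling, the expression filter, the robust moderation, the groups in the model, the replicate number as a block and the required fold change, tried voom with sample quality weights, run here on recovered reads, and left out each library in turn. Other pseudocounts, no scaling, a filter at RPKM 5, array weights, a correction of each library for smooth trends on gene length and GC, and fits without 2 libraries with muscle transcripts or without the 2 libraries farthest apart on the second principal component were added after the data had been seen. The 2 libraries apart on that component were naive replicate 1 (28.54) and day 7 replicate 1 (-32.89). The procedure was tested on simulated data with known changes drawn from the means and library sizes of these data. Reads of genes with near-identical copies, such as C4b and the Mrgpr, histone and ribosomal protein families, can be split or shared by counting, so the levels of such genes are uncertain. Behavioural measurements and other days of the time course were not used here.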

Results

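The series measured RNA in dorsal root ganglia, which hold the cell bodies of sensory neurons, of adult male C57BL/6J mice. The animals were naive or had spared nerve injury, a model of neuropathic pain in which 2 of the 3 branches of the sciatic nerve, the tibial and the common peroneal, are tied and severed and the sural branch is left intact. Ganglia were taken from naive mice and at days 1, 3 and 7 after injury, with 3 RNA-seq libraries in each of the 4 groups. Per the design text the study set expression over time beside pain behaviour, and the comparisons below ask how each day differed from naive and how the days differed from each other. No sham-operated group was analysed here, so surgery and nerve damage were compared with naive together.

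Library size, recovered from the steps between low RPKM values, was 14333000, 16785000 and 15178000 reads in naive replicates 1, 2 and 3 and 15938000, 14591000 and 17953000 reads at day 1. It was 16032000, 15810000 and 15182000 reads at day 3 and 16143000, 17674000 and 13627000 reads at day 7. Pearson's r of log2 values across genes between replicates lay between 0.953 and 0.976, and no pair of replicates agreed within sampling noise. Skeletal muscle transcripts were higher in naive replicate 1 and day 7 replicate 2 than elsewhere. Myh4, a fast myosin heavy chain, stood at 9.75 and 10.25 RPKM there and at 2.59 RPKM or less in the other 10 libraries. The labels do not say whether each library came from 1 animal or a pool, so p-values measure the spread between these samples.

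Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and all 14195 genes that passed the expression filter were tested with limma. In mm10 coordinates from GENCODE M21, the gene followed most closely, Atf3, lies on chromosome 1 from 191170296 to 191218039. Sprr1a lies on chromosome 3 from 92483952 to 92485895, and Csf1 on chromosome 3 from 107741048 to 107760469. Gal lies on chromosome 19 from 3409915 to 3414544, Npy on chromosome 6 from 49822710 to 49829507, and Sox11 on chromosome 12 from 27334264 to 27342574. Gap43 lies on chromosome 16 from 42248442 to 42340651, and Scn10a on chromosome 9 from 119608456 to 119719322. All 8 are annotated as protein-coding, and each value covers the whole gene.

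One day after injury, transcripts of the axotomy response stood far above naive. Atf3, a stress-induced transcription factor, rose from 2.38 ± 0.144 to 70.1 ± 8.49 RPKM (SD, n = 3), a log2 fold change of 4.61 (SE 0.14, adjusted p = 2.16e-10). Sox11, a transcription factor of axon growth, rose by 2.64 (SE 0.18) from 3.69 ± 0.322 to 25.8 ± 5.1 RPKM, and Csf1, the macrophage and microglia growth factor, rose by 1.92 (SE 0.13) from 2.38 ± 0.373 to 10.3 ± 0.852 RPKM, each with an adjusted p of 1.36e-06. The neuropeptide Gal rose by 2.62 (SE 0.25) from 2.29 ± 0.408 to 16.8 ± 3.5 RPKM (adjusted p = 7.9e-05). Npy, a neuropeptide near the detection limit in naive ganglia at 0.242 ± 0.324 RPKM, reached 6.45 ± 1.91 RPKM with a log2 fold change of 3.28 (SE 0.28). Gap43, a growth cone protein, stood at 61.7 ± 14.9 RPKM against 34.7 ± 6.7 RPKM in naive and did not pass (log2 fold change 0.81, adjusted p = 0.0704).

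Among the other genes with the largest rises at day 1 were Gadd45a, a DNA damage and stress gene, at 3.04 (SE 0.26), the semaphorin Sema6a at 2.68 (SE 0.16) and the orphan receptor Gpr151 at 2.51 (SE 0.31). Smim3 rose by 2.47 (SE 0.25), and Igfbp3, which binds insulin-like growth factors, by 2.37 (SE 0.21). Sprr1a, a small proline-rich protein of growing axons, rose by 3.02 (SE 0.53, adjusted p = 0.0142) with wide spread, from 2.24 ± 0.92 to 25.6 ± 19.9 RPKM. The call for Sprr1a ended without naive replicate 1 (adjusted p = 0.0557), without naive replicate 3 (0.0664), with voom on recovered reads (0.0522), without the 2 libraries with muscle transcripts (0.0704), without the 2 libraries apart on principal component 2 (0.0605) and when those 2 groups alone were fitted (0.0932).

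The largest falls at day 1 were smaller. The Mas-related receptor Mrgprb5 fell by 1.64 (SE 0.26, adjusted p = 0.0041), from 32.0 ± 3.77 to 10.5 ± 4.28 RPKM, and Chrna6, a nicotinic receptor subunit, fell by 1.36 (SE 0.16), from 12.4 ± 0.266 to 4.58 ± 0.868 RPKM. Vwc2l fell by 1.06 (SE 0.16), the transcription factor Onecut1 by 1.04 (SE 0.18) and Rab27b, a GTPase of vesicle secretion, by 1.01 (SE 0.16). St6gal2 and Pnpla3 had log2 fold changes of -0.97 and -0.94. Pmp2, a lipid-binding myelin protein, fell by 1.41 (SE 0.29, adjusted p = 0.0186), a call lost without naive replicate 1 (0.0719), naive replicate 3 (0.0624), day 1 replicate 1 (0.0907) or day 1 replicate 2 (0.0559) and without the 2 libraries with muscle transcripts (0.0989). Slc16a12 fell by 0.92, a call lost without day 1 replicate 1 (adjusted p = 0.0515). By the rule for named genes, all 3 day 1 libraries lay on the same side of all 3 naive libraries for each gene of these rises and falls.

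**Figure D1:**
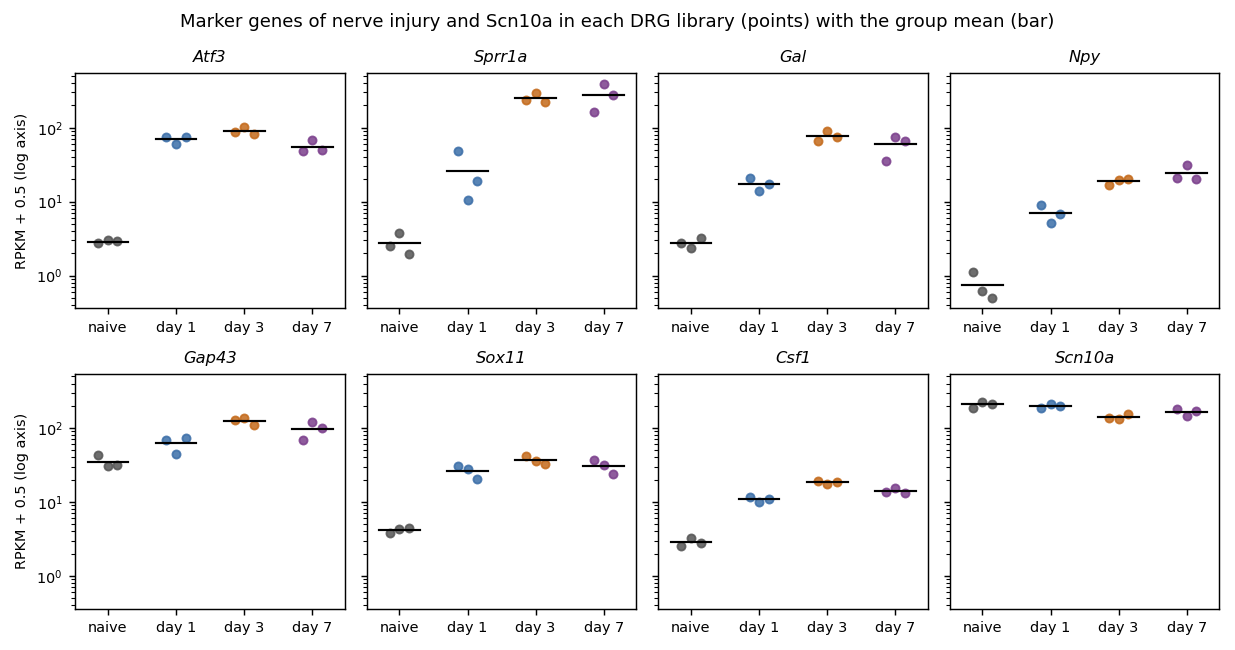
RPKM + 0.5 on a log axis for the 8 genes fixed in advance, with 1 point per library, 3 libraries in each of the 4 groups, and a bar at each group mean. Atf3 goes from a mean of 2.38 RPKM in naive libraries to 70.1, 89.7 and 54.9 RPKM at days 1, 3 and 7, while Sprr1a reaches 252 RPKM at day 3 after 25.6 RPKM at day 1.

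Of the 23 tested genes known to be induced in axotomised neurons, 19 rose at day 1, none fell and 4 did not pass (22 adjusted over the list alone), with a median log2 fold change of 1.92 (camera adjusted p = 1.53e-42, and adjusted p = 0.0158 with an estimated correlation). Among them was Flrt3, an adhesion protein of axon guidance, at 2.29. Of 12 immediate early genes, 2 rose, Fosl2 by 1.77 and the phosphatase Dusp1 by 1.03, and the list was called higher (2 adjusted over the list alone, adjusted p = 3.91e-05, but adjusted p = 0.1 with an estimated correlation). Of 13 tested cytokines and chemokines, out of 33 listed, only Csf1 rose (2 adjusted over the list alone, median 0.22, adjusted p = 0.021, but adjusted p = 0.1 with an estimated correlation). Of 16 heat shock and endoplasmic reticulum stress genes 1 rose, the pseudokinase Trib3 at 1.03 (4 adjusted over the list alone, adjusted p = 0.0222, but adjusted p = 0.783 with an estimated correlation). Calls ended without naive replicate 2 for cytokines (0.0591) and stress genes (0.0941), without day 1 replicate 2 for cytokines (0.0603), and without day 1 replicate 3 (0.242) or with a filter at RPKM 5 (0.136) for stress genes. Trib3 itself no longer passed without naive replicate 1 (0.0902), naive replicate 3 (0.0751), day 1 replicate 1 (0.132) or day 1 replicate 2 (0.0533).

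The synaptic transmission, nociceptor, potassium channel and mechanoreceptor lists lay lower at day 1. Of 24 genes of synaptic transmission 5 fell (7 adjusted over the list alone), among them Chrna6 and Gria2, a glutamate receptor subunit with a log2 fold change of -0.76, and the list median was -0.29 (adjusted p = 3.77e-06, but adjusted p = 0.0928 with an estimated correlation). Of 24 receptors and peptides of uninjured nociceptors 5 fell and none rose (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.000108, but adjusted p = 0.144 with an estimated correlation). None of 31 potassium channel genes passed in limma, over all genes or adjusted over the list alone (12 at an unadjusted p under 0.05, while 1 rose and 11 fell with voom), and the list median of -0.22 was called lower (adjusted p = 0.000585, but adjusted p = 0.0928 with an estimated correlation). Of 15 genes of mechanoreceptors and proprioceptors 1 fell (1 adjusted over the list alone, adjusted p = 0.0356, but adjusted p = 0.127 with an estimated correlation). That list's call ended without naive replicate 2 (0.0941), day 1 replicate 1 (0.0952) or day 1 replicate 2 (0.0926), with a filter at RPKM 5 (0.137) and with no scaling (0.051). Of 23 sodium and calcium channel genes limma called 0 (10 at an unadjusted p under 0.05, while 3 rose and 4 fell with voom, and 2 rose and 2 fell adjusted over the list alone), and the list, with a median of -0.09, was not called (adjusted p = 0.316).

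In all, limma called 489 genes at day 1, 371 higher and 118 lower, of which 142 rose and 10 fell at least 2-fold. The count was 284, 290 and 248 without naive replicate 1, 2 or 3 and 218 without day 1 replicate 1. It was 277 without the 2 libraries with muscle transcripts, 836 after a gene length and GC correction, 1558 with voom on recovered reads and 1836 with array weights. Higher genes made up 75.9% of the calls, against 63% after the length and GC correction, 57.3% with voom and 56.5% with array weights, and 71.8% to 84.3% with 1 library left out. In place of 118, lower genes numbered 52, 48 and 39 without naive replicates 1, 2 and 3, 36 and 73 without day 1 replicates 1 and 3, and 49 without the 2 libraries with muscle transcripts.

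At day 3 transcripts of the axotomy response stood above naive. Sprr1a reached 252 ± 37.5 RPKM from 2.24 ± 0.92 RPKM, a log2 fold change of 6.57 (SE 0.53, adjusted p = 8.28e-05). Atf3 stood at 89.7 ± 10 RPKM, a rise of 4.96 (SE 0.14, adjusted p = 7.73e-11), and Gal at 77.1 ± 12.1 RPKM, a rise of 4.80 (SE 0.25). Npy rose by 4.77 (SE 0.28) to 18.6 ± 1.8 RPKM, Sox11 by 3.13 (SE 0.18) and Csf1 by 2.68 (SE 0.13) to 17.9 ± 1.0 RPKM. Gap43 passed at this day, rising from 34.7 ± 6.7 to 126 ± 14.3 RPKM (log2 fold change 1.85, SE 0.22, adjusted p = 0.000191), while its difference between day 1 and day 3 did not pass (adjusted p = 0.0622). Gpr151 rose by 4.01 (SE 0.31), the neuropeptide Nts by 3.51 (SE 0.29), Sez6l by 3.33 (SE 0.15), the activin antagonist Fst by 3.24 (SE 0.21) and Lmo7 by 3.01 (SE 0.14).

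Receptor genes stood among the largest falls at day 3. Mrgprb5 fell by 1.33 (SE 0.26), the muscarinic receptor Chrm2 by 1.18 (SE 0.22), and the nicotinic subunits Chrna6 and Chrna7 by 1.04 (SE 0.16) and 0.97 (SE 0.19). Dpp10, an auxiliary subunit of Kv4 potassium channels, fell by 1.16 (SE 0.13, adjusted p = 0.000103), from 50.1 ± 2.82 to 22.2 ± 1.54 RPKM. Ano3, a member of the anoctamin family, fell by 0.94 (SE 0.16) from 159 ± 12.5 to 82.5 ± 3.61 RPKM, and Tmem255a by 0.96 (SE 0.1) from 65.6 ± 0.253 to 33.4 ± 1.99 RPKM. Vwc2l and Ankrd34c fell by 1.06 and 1.01, and the GABA receptor subunit Gabrb2 by 0.98, a call lost without naive replicate 2 (adjusted p = 0.0677), naive replicate 3 (0.0636) or day 3 replicate 2 (0.0538). Scn10a, the nociceptor sodium channel Nav1.8, fell by 0.56 (SE 0.13, adjusted p = 0.0181) from 209 ± 19.1 to 141 ± 12.3 RPKM. Its call ended without naive replicate 2 (0.0875), naive replicate 3 (0.0773), day 3 replicate 1 (0.0633) or day 3 replicate 2 (0.0937).

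Of the 23 injury-induced genes 21 rose at day 3 and 2 did not pass (22 rose adjusted over the list alone), with a median of 2.68 (camera adjusted p = 3.07e-50, and adjusted p = 0.00906 with an estimated correlation). Of 20 macrophage markers 7 rose and none fell (16 rose adjusted over the list alone), with a median of 0.85 (adjusted p = 4.26e-11, and adjusted p = 0.0432 with an estimated correlation). The mannose receptor Mrc1 rose by 1.33 and the protease Ctss by 1.25. Of 12 complement genes 4 rose, including C4b by 0.90 and C3 by 1.33, while Cd55, a complement inhibitor, fell by 0.72 (4 rose and 1 fell adjusted over the list alone). The complement list was called higher (adjusted p = 0.0043, but adjusted p = 0.152 with an estimated correlation), and was not called with a filter at RPKM 5 (adjusted p = 0.28). Reads of C4b can be shared with its near-identical neighbour C4a, so its level is uncertain. Of 13 cytokines and chemokines only Csf1 rose (1 adjusted over the list alone), and the list was called higher (adjusted p = 0.00334, and adjusted p = 0.0444 with an estimated correlation).

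Channel and receptor lists lay lower at day 3. Of 31 potassium channel genes 8 fell and none rose (16 fell and 1 rose adjusted over the list alone), with a median of -0.41 (adjusted p = 1.37e-08, and adjusted p = 0.011 with an estimated correlation). Kcnh7 fell by 0.89. Of 24 genes of synaptic transmission 8 fell (12 fell and 1 rose adjusted over the list alone), with a median of -0.44 (adjusted p = 5.5e-08, and adjusted p = 0.0257 with an estimated correlation). Gria2 fell by 0.77. Of 15 mechanoreceptor and proprioceptor genes 3 fell (4 fell and 1 rose adjusted over the list alone), Etv1, a transcription factor of proprioceptors, by 0.86, and the list was called lower (adjusted p = 2.66e-05, and adjusted p = 0.0139 with an estimated correlation). Of 24 nociceptor genes 7 fell and 1 rose (12 and 2 adjusted over the list alone), with Mrgprd at -0.68 and Mrgprb4 at -0.73 (adjusted p = 4.29e-07, but adjusted p = 0.0558 with an estimated correlation). Members of the Mrgpr family resemble each other in sequence, so reads can be split between them.

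Of 23 sodium and calcium channel genes 6 fell at day 3 and 1 rose (10 and 1 adjusted over the list alone). Scn1a fell by 0.87, Scn11a, the channel Nav1.9, by 0.63 and the beta subunit Scn4b by 0.59, while Cacna2d1, the calcium channel subunit bound by gabapentin, rose by 1.46. The list was called lower (adjusted p = 0.000211, but adjusted p = 0.152 with an estimated correlation). Of 19 general sensory neuron markers 2 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of -0.18 and a mean of 0.01, and the list was not called (adjusted p = 0.685). Elavl3, a neuronal RNA-binding protein, rose by 0.54.

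Of 24 genes of cholesterol synthesis 2 rose at day 3 (4 adjusted over the list alone), Hsd17b7 by 1.23 (list adjusted p = 0.00278, but adjusted p = 0.462 with an estimated correlation). Of 15 cell division genes 1 rose (4 adjusted over the list alone, median 0.43, adjusted p = 0.00102, but adjusted p = 0.13 with an estimated correlation). Of 12 immediate early genes 2 rose, Fosl2 by 1.32 and Dusp1 by 1.03 (2 adjusted over the list alone, adjusted p = 0.0191, but adjusted p = 0.333 with an estimated correlation), and the list was not called after the length and GC correction (0.061). Of 16 stress genes 3 rose (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.0343, but adjusted p = 0.636 with an estimated correlation). That call ended without naive replicate 2 (0.112), day 3 replicate 2 (0.224) or day 3 replicate 3 (0.0872), with no expression filter (0.0626), with a filter at RPKM 5 (0.28) and after the length and GC correction (0.11). Of 80 ribosomal protein genes 1 rose (0 adjusted over the list alone) while the median was 0.31 (adjusted p = 2.18e-06, but adjusted p = 0.66 with an estimated correlation). The mean of that list differed by 0.35 between day 3 and naive and ranged over 0.54 within day 3 and 0.48 within naive.

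In all, 799 genes were called at day 3, 527 higher and 272 lower, of which 232 rose and 16 fell at least 2-fold. The count was 452 without naive replicate 2, 449 without naive replicate 3, 515 without day 3 replicate 1 and 484 without day 3 replicate 2. It was 1347 after the length and GC correction, 2258 with voom on recovered reads and 1947 with array weights. Higher genes made up 66% of the calls, against 53.5% after the length and GC correction, 53.4% with voom and 55.9% with array weights, and 59.5% to 74.8% with 1 library left out. In place of 272, lower genes numbered 114 and 115 without naive replicates 2 and 3, 157, 137 and 158 without day 3 replicates 1, 2 and 3, 438 without day 7 replicate 1 and 468 when naive and day 3 alone were fitted.

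**Figure D2:**
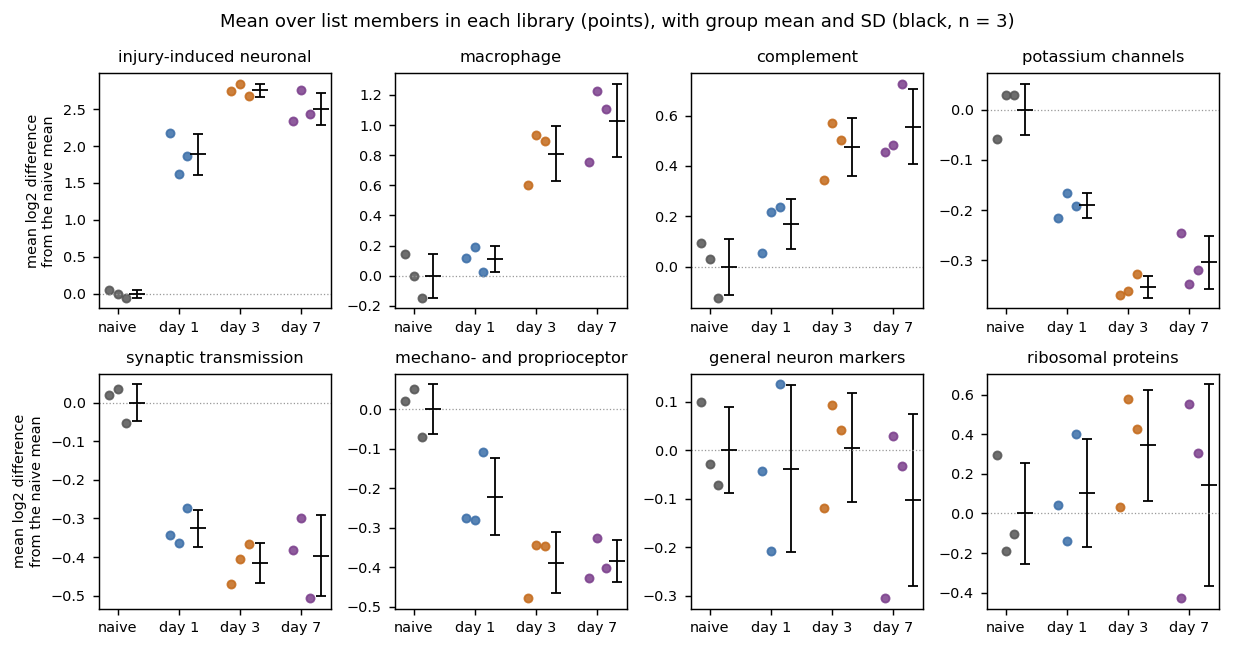
Mean log2 difference from the naive mean for each of 8 gene lists in each of the 12 libraries, with 1 coloured point per library and the mean and SD of 3 libraries in black. The injury-induced list lies above naive at every day after injury, the macrophage list at days 3 and 7, and the potassium channel and synaptic lists lie below naive.

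Transcripts of the axotomy response also stood above naive at day 7. Sprr1a stood at 277 ± 114 RPKM, a log2 fold change of 6.63 (SE 0.53, adjusted p = 0.000114), and Npy at 23.9 ± 6.39 RPKM, a rise of 5.09 (SE 0.28, adjusted p = 4.48e-07). Gal rose by 4.35 (SE 0.25) to 58.9 ± 20.8 RPKM, Atf3 by 4.25 (SE 0.14) to 54.9 ± 10.8 RPKM, Sox11 by 2.87 (SE 0.18) and Csf1 by 2.30 (SE 0.13) to 13.7 ± 1.21 RPKM. Gap43 rose by 1.44 (SE 0.22, adjusted p = 0.00217). Gpr151 and Nts rose by 3.55 (SE 0.31) and 3.47 (SE 0.29), Sez6l by 3.10 (SE 0.15), Fst by 2.81 (SE 0.21) and Lmo7 by 2.74 (SE 0.14). Scn10a stood at 165 ± 19.4 RPKM against 209 ± 19.1 RPKM in naive and did not pass (log2 fold change -0.34, adjusted p = 0.239).

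Among the falls at day 7 taken by the rule for named genes, the largest was that of Htr3a, a serotonin-gated channel, at -1.14 (SE 0.24, adjusted p = 0.0196), from 17.5 ± 2.77 to 7.95 ± 2.72 RPKM. Its call ended without naive replicate 1 (0.0901), 2 (0.0642) or 3 (0.0547), and in 4 other alternatives at 0.0524 to 0.0951. Vwc2l and Fam81a fell by 0.97 and 0.94, calls lost only without the 2 libraries with muscle transcripts (adjusted p = 0.053 for both). Pnpla3 fell by 0.90, a call lost without naive replicate 2 (0.0506), Kcnh7 by 0.86, lost without naive replicate 3 (0.0566), and Rnf112 by 0.83, lost without naive replicate 1 (0.0503). Lgi3 fell by 0.88, a call lost without naive replicate 1 (0.062), naive replicate 3 (0.0914) or day 7 replicate 1 (0.0502). The adhesion gene Cdh12 fell by 0.88, lost without naive replicate 2 (0.079), naive replicate 3 (0.078), day 7 replicate 2 (0.0526) or day 7 replicate 3 (0.0716). Chrna7 fell by 0.83, lost without naive replicate 2 (0.131), naive replicate 3 (0.131), day 7 replicate 2 (0.0896) or day 7 replicate 3 (0.107). Without the 2 libraries with muscle transcripts, Kcnh7, Rnf112, Lgi3, Cdh12 and Chrna7 had adjusted p values of 0.0651, 0.104, 0.0819, 0.0557 and 0.0587.

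Of the 23 injury-induced genes 21 rose at day 7 (21 adjusted over the list alone), with a median of 2.33 (camera adjusted p = 5.38e-58, and adjusted p = 0.00504 with an estimated correlation). Of 20 macrophage markers 10 rose (17 adjusted over the list alone), with a median of 1.12 (adjusted p = 1.11e-19, and adjusted p = 0.00813 with an estimated correlation). Ctss rose by 1.92, the receptor of colony-stimulating factor 1, Csf1r, by 1.38, Mrc1 by 1.21 and the perforin-like Mpeg1 by 1.17. Of 13 cytokines and chemokines 2 rose, Csf1 and the alarmin Il33, the latter by 0.82 (5 adjusted over the list alone, adjusted p = 2.23e-06, and adjusted p = 0.00504 with an estimated correlation). Il33 no longer passed without naive replicate 2 (0.0824), naive replicate 3 (0.0662) or day 7 replicate 3 (0.0514). Of 12 complement genes 5 rose, C4b by 0.85, C3 by 1.13 and C1qc by 1.62 (6 adjusted over the list alone, adjusted p = 0.000162, but adjusted p = 0.0758 with an estimated correlation).

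Of 21 fibroblast and matrix genes 1 rose at day 7, the collagen cross-linking enzyme Loxl2, by 1.95 (1 adjusted over the list alone, median 0.26, adjusted p = 0.000145, but adjusted p = 0.0859 with an estimated correlation). No antigen presentation gene of 17 passed in limma (5 at an unadjusted p under 0.05, 5 rose with voom, and 3 rose adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0094, but adjusted p = 0.277 with an estimated correlation). Of 24 interferon-stimulated genes 1 rose (2 adjusted over the list alone, adjusted p = 0.00911, but adjusted p = 0.476 with an estimated correlation). Without naive replicate 2 the adjusted p was 0.0683 for antigen presentation and 0.176 for the interferon list, and without day 7 replicate 3 it was 0.0754 and 0.117. None of 15 cell division genes passed in limma (4 at an unadjusted p under 0.05, 3 rose with voom, and 3 rose adjusted over the list alone), with a median of 0.35 (adjusted p = 0.00107, but adjusted p = 0.112 with an estimated correlation, 0.166 without the 2 libraries with muscle transcripts and 0.0524 without the 2 apart on component 2). Of 12 immediate early genes 1 rose, Fosl2 by 1.03 (1 adjusted over the list alone, adjusted p = 0.0094, but adjusted p = 0.249 with an estimated correlation), a list call lost without day 7 replicate 2 (0.0787).

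Of 31 potassium channel genes 2 fell at day 7 (10 adjusted over the list alone), Kcnh7 and Kcns3, with a list median of -0.33 (adjusted p = 3.65e-09, and adjusted p = 0.00504 with an estimated correlation). Of 24 genes of synaptic transmission 3 fell (12 adjusted over the list alone), including Chrna6 by 0.80, with a median of -0.44 (adjusted p = 2.3e-09, and adjusted p = 0.01 with an estimated correlation). Of 15 mechanoreceptor and proprioceptor genes 1 fell (8 adjusted over the list alone, adjusted p = 1.65e-06, and adjusted p = 0.00504 with an estimated correlation). Of 24 nociceptor genes 2 fell (4 fell and 2 rose adjusted over the list alone, adjusted p = 9.78e-05, but adjusted p = 0.112 with an estimated correlation). Of 23 sodium and calcium channel genes 2 fell, including Scn4b by 0.55, and Cacna2d1 rose by 1.25 (4 and 1 adjusted over the list alone, adjusted p = 0.000635, but adjusted p = 0.174 with an estimated correlation). Kcns3, at -0.59, no longer passed without naive replicate 2 (0.0601) or naive replicate 3 (0.0613), and Kcnh7 without naive replicate 3 (0.0566). Scn4b no longer passed without the 2 libraries with muscle transcripts (0.0511) or when naive and day 7 alone were fitted (0.0662).

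The ribosomal protein list, with no member of 80 passing in limma (2 at an unadjusted p under 0.05, 1 by voom), was called higher at day 7 (median 0.14, adjusted p = 0.0471, but adjusted p = 0.893 with an estimated correlation). Its call ended without naive replicate 2 (0.727), naive replicate 3 (0.331), day 1 replicate 1 (0.0509) or day 7 replicate 3 (0.605), and without day 7 replicate 2 its median was -0.07 (0.298). It also ended with a pseudocount of 0.1 (0.0512), with no scaling (0.153), after the length and GC correction (0.0777) and without the 2 libraries with muscle transcripts (0.234). In all, 415 genes were called at day 7, 330 higher and 85 lower, of which 181 rose and 6 fell at least 2-fold. The count was 239 without naive replicate 2, 235 without naive replicate 3, 166 without the 2 libraries with muscle transcripts and 256 when naive and day 7 alone were fitted. It was 880 after the length and GC correction, 939 with voom on recovered reads and 833 with array weights. Higher genes made up 79.5% of the calls, against 52.3% after the length and GC correction, 58.7% with voom and 61.3% with array weights, and 64.5% to 91.9% with 1 library left out. In place of 85, lower genes numbered 48, 25 and 19 without naive replicates 1, 2 and 3, and 184 and 45 without day 7 replicates 1 and 3. They numbered 13 without the 2 libraries with muscle transcripts (92.2% higher), 230 without the 2 apart on component 2 (60.7% higher) and 35 when naive and day 7 alone were fitted.

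Between day 1 and day 3, Gal, Nts, Sprr1a and Npy rose. Gal rose by 2.17 (SE 0.25, adjusted p = 0.0041), from 16.8 ± 3.5 to 77.1 ± 12.1 RPKM, and Nts by 2.20 (SE 0.29, adjusted p = 0.00673), a call lost without day 1 replicate 3 (0.0606). Sprr1a rose by 3.55 (SE 0.53, adjusted p = 0.0287), Car3, a carbonic anhydrase, by 1.99 (SE 0.33, adjusted p = 0.0265), Npy by 1.49 (SE 0.28, adjusted p = 0.04) and Csf1 by 0.77 (SE 0.13, adjusted p = 0.022). Fam150b, a ligand of the kinases Alk and Ltk, fell by 1.46 (SE 0.23), the phosphodiesterase Pde4c by 0.95 (SE 0.16) and Fkbp5, a glucocorticoid target, by 0.77 (SE 0.15). Olfr920, of the olfactory receptor family whose members resemble each other, fell by 1.03 (SE 0.18), and the receptor Lpar5 by 1.01 (SE 0.21). The calls of these 8 genes other than Gal and Nts among the 10 named by rank, and of Csf1, were lost in 3 to 10 of the 12 leave-one-out fits.

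Without day 3 replicate 2 the adjusted p was 0.129 for Sprr1a, 0.114 for Car3, 0.148 for Npy, 0.0534 for Fam150b, 0.0908 for Olfr920, 0.218 for Lpar5, 0.0909 for Pde4c, 0.148 for Fkbp5 and 0.0792 for Csf1. Without day 1 replicate 2 it was 0.0595 for Sprr1a, 0.109 for Car3, 0.152 for Npy, 0.0625 for Fam150b, 0.115 for Olfr920, 0.196 for Lpar5, 0.109 for Pde4c, 0.109 for Fkbp5 and 0.0876 for Csf1. Without day 1 replicate 3 it was 0.114 for Sprr1a, 0.143 for Npy and for Lpar5, 0.0894 for Pde4c, 0.144 for Fkbp5 and 0.075 for Csf1. Without day 1 replicate 1 it was 0.0937 for Car3 and Lpar5, 0.0609 for Fam150b, 0.113 for Olfr920, 0.0669 for Pde4c and 0.12 for Fkbp5. Without day 3 replicate 1 it was 0.0974 for Sprr1a, 0.0921 for Car3, 0.113 for Npy, 0.0876 for Olfr920, 0.19 for Lpar5, 0.107 for Fkbp5 and 0.0898 for Csf1. Without day 3 replicate 3 it was 0.0982 for Sprr1a, 0.111 for Car3 and Pde4c, 0.146 for Npy, 0.124 for Olfr920, 0.155 for Fkbp5 and 0.0942 for Csf1. Leaving out a library of another group also ended calls of Sprr1a, Npy, Fkbp5 and Lpar5, with values given further below. A pseudocount of 0.1 moved Npy to an adjusted p of 0.411, and with no scaling the adjusted p was 0.124 for Lpar5 and 0.136 for Fkbp5.

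Of the 23 injury-induced genes 7 rose between day 1 and day 3 (16 adjusted over the list alone), including Anxa1, an annexin, by 1.47 (median 0.77, camera adjusted p = 4.27e-19, but adjusted p = 0.0776 with an estimated correlation). Of 20 macrophage markers 4 rose (14 adjusted over the list alone), Mrc1 by 1.21, a call lost without day 3 replicate 2 (0.0534), with a list median of 0.76 (adjusted p = 1.08e-14, but adjusted p = 0.0776 with an estimated correlation). Potassium channels had a median of -0.19 with no member passing in limma, over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, while 2 fell with voom; adjusted p = 0.000407, but adjusted p = 0.0776 with an estimated correlation). Camera called 13 of the 29 lists, 9 higher and 4 lower, against 0 with an estimated correlation, the count of lists at 10 to 13 in leave-one-out fits. In all, 72 genes were called, 54 higher and 18 lower (1339 at an unadjusted p under 0.05). The share higher was 75%, against 87.9% with no scaling between libraries, 61.2% after the length and GC correction, 58.3% with voom and 57.3% with array weights, and 73.6% to 100% with 1 library left out. In place of 18, limma called 0 lower genes without day 1 replicate 1 or day 3 replicate 2 (511 and 426 at an unadjusted p under 0.05), where voom and array weights on all libraries called 160 and 149. Lower genes numbered 8, 5 and 5 without naive replicates 1, 2 and 3, 1 and 2 without day 1 replicates 2 and 3, 6 and 4 without day 3 replicates 1 and 3, 28 without day 7 replicate 1 and 6 without the 2 libraries with muscle transcripts. They numbered 3 with the replicate block (90.3% higher), 7 with no scaling, 8 with a filter at RPKM 5 and 11 with a pseudocount of 0.1. After the length and GC correction they numbered 64. The count was 43 and 41 without naive replicates 2 and 3, 32, 22 and 17 without day 1 replicates 1, 2 and 3, and 23, 13 and 25 without day 3 replicates 1, 2 and 3. It was 47 with a filter at RPKM 5, 165 after the length and GC correction, 384 with voom and 349 with array weights.

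Between day 1 and day 7, macrophage and matrix genes were among those that rose. Ctss rose by 1.70 (SE 0.2, adjusted p = 0.00348), from 4.19 ± 0.508 to 15.2 ± 4.46 RPKM, Csf1r by 1.42, Mpeg1 by 1.21 and Ms4a7 by 1.67. Of 20 macrophage markers 6 rose (14 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 5.88e-20, and adjusted p = 0.0371 with an estimated correlation). Of 21 fibroblast and matrix genes 3 rose and 1 fell (11 and 2 adjusted over the list alone), Loxl2 by 1.79 and the collagen Col3a1 by 0.97 (adjusted p = 4.66e-07, but adjusted p = 0.0873 with an estimated correlation). Of the 23 injury-induced genes 6 rose and 1 fell (12 and 4 adjusted over the list alone, adjusted p = 4.66e-07, but adjusted p = 0.246 with an estimated correlation). Nts, Npy and Gal rose by 2.16, 1.82 and 1.73, and Npy did not pass with a pseudocount of 0.1 (adjusted p = 0.232). Sprr1a rose by 3.61, a call lost without day 1 replicate 3 (0.075), day 7 replicate 2 (0.0687) or day 7 replicate 3 (0.0546).

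Adcyap1, the neuropeptide PACAP, fell by 1.10 (SE 0.18, adjusted p = 0.00996) between day 1 and day 7, from 80.6 ± 15.2 to 38.1 ± 10.9 RPKM, a call lost when those 2 groups alone were fitted (0.0957). Fam150b fell by 1.76 (SE 0.23, adjusted p = 0.00348), Pde4c by 1.09 (SE 0.16) and the growth factor Bdnf by 1.01. Tmem79 fell by 1.08, a call lost without day 1 replicate 1 (0.0534) or day 1 replicate 3 (0.0871). Asphd1 fell by 1.10 (adjusted p = 0.0357), a call lost without naive replicate 1 (0.0532), day 1 replicate 1 (0.118), day 1 replicate 3 (0.15), day 3 replicate 1 (0.052), day 3 replicate 2 (0.0579), day 7 replicate 1 (0.0977) or day 7 replicate 3 (0.114), and with voom (0.165). In all, 138 genes were called, 87 higher and 51 lower, and the share higher was 63.0%, against 73.4% with no scaling between libraries, 50.2% after the length and GC correction, 60.9% with voom and 56.5% with array weights, and 60.0% to 78.8% with 1 library left out. In place of 51, lower genes numbered 14, 28 and 18 without day 1 replicates 1, 2 and 3, 33 without day 3 replicate 2, 20 and 22 without day 7 replicates 2 and 3, 21 without the 2 libraries with muscle transcripts and 11 when those 2 groups alone were fitted. The count was 66, 82 and 54 without day 1 replicates 1, 2 and 3, 62 and 70 without day 7 replicates 2 and 3, 57 without the 2 libraries with muscle transcripts and 38 when those 2 groups alone were fitted. It was 283 after the length and GC correction, 299 with voom and 294 with array weights. Camera called 14 lists, 9 higher and 5 lower, against 1 with an estimated correlation, the macrophage list, and against 6 without day 7 replicate 3 and 9 with a filter at RPKM 5.

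Between day 3 and day 7 no gene passed. Limma called 0 genes (718 at an unadjusted p under 0.05), as did voom on recovered reads and limma with array weights. Atf3 stood at 89.7 ± 10 and 54.9 ± 10.8 RPKM at the 2 days (log2 fold change -0.71, adjusted p = 0.497), Sprr1a at 252 ± 37.5 and 277 ± 114 RPKM, and Gal at 77.1 ± 12.1 and 58.9 ± 20.8 RPKM. The injury-induced list had a median of -0.21 with no member passing (2 fell adjusted over the list alone; camera adjusted p = 6.56e-06, but adjusted p = 0.496 with an estimated correlation). The macrophage list had a median of 0.19 (2 rose adjusted over the list alone, adjusted p = 0.00172, but adjusted p = 0.496 with an estimated correlation), a call lost without day 3 replicate 1 (0.178), day 7 replicate 2 (0.167) or day 7 replicate 3 (0.0807) and without the 2 libraries with muscle transcripts (0.149). Camera called 8 of 29 lists, 4 higher and 4 lower, against 0 with an estimated correlation and 4 without day 7 replicate 3. Leaving out day 1 replicate 1 gave 2 genes, the length and GC correction gave 2, no expression filter gave 4, and fitting days 3 and 7 alone gave 1.

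A test for any difference between the 4 groups called 679 genes, against 450, 383 and 388 without naive replicates 1, 2 and 3, 405 without the 2 libraries with muscle transcripts, 1247 after the length and GC correction, 2319 with voom and 2101 with array weights. Against naive, 186 genes were higher and 27 lower at all 3 days, and none was called in opposite directions at day 1 and day 7. Days 1 and 3 shared 271 higher and 73 lower genes, where independent lists would share 13.8 and 2.3. Days 3 and 7 shared 294 and 69, against 12.3 and 1.6, and days 1 and 7 shared 186 and 28, against 8.6 and 0.7. All 3 comparisons used the same 3 naive libraries. In 20 simulations of unchanged groups against shared controls 0 calls were shared. With nothing truly changed few calls could arise, so this 0 cannot weigh the overlaps. Genes varied independently, so the simulated values below leave out shifts of many genes in 1 library. Across genes, which are not independent replicates, the correlation of fold changes was 0.688 for days 1 and 3, 0.763 for days 3 and 7 and 0.621 for days 1 and 7, against 0.501, 0.506 and 0.499 in the simulations. The covariances were 0.0967, 0.110 and 0.0794, against 0.0333, 0.0335 and 0.033. The 3 naive libraries could not be split into parts of 2, so part of the excess may come from the shared controls.

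**Figure D3:**
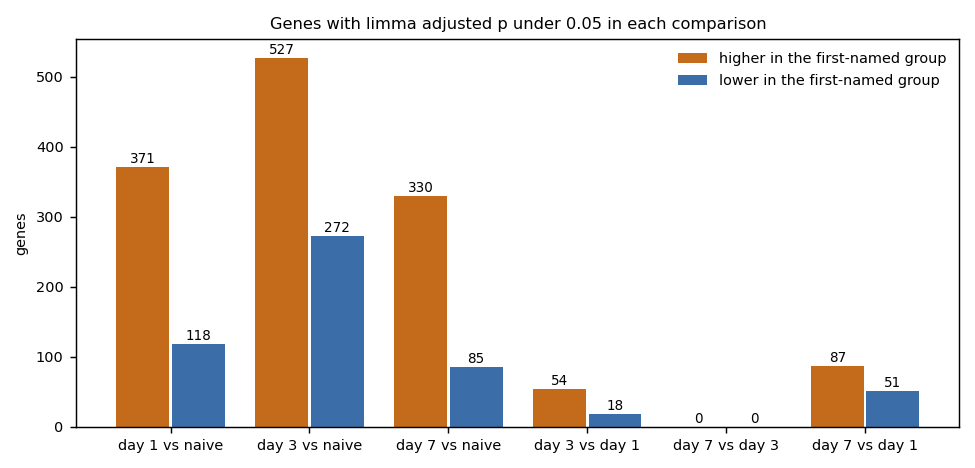
Number of genes called higher and lower, as bars side by side, by limma at an adjusted p under 0.05 in each of the 6 comparisons. The count is 489 at day 1, 799 at day 3 and 415 at day 7 against naive, 72 between days 1 and 3, 138 between days 1 and 7 and 0 between days 3 and 7.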

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

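The results below are genes named in the text and 1 list for which the difference between 2 injured days itself passed, so that their changes from naive differed between those days. A gene named only as a member of a list is given for a comparison in which the rule for named genes took it. These comparisons between days were fixed beforehand, and no test of an explanation was run on them. All of the genes were tested with limma, and each bracketed value is the adjusted p without the library named.

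From day 1 to day 3, the log2 fold change was 3.55 for Sprr1a, 2.20 for Nts, 2.17 for Gal, 1.99 for Car3, 1.49 for Npy, 1.47 for Anxa1, 1.21 for Mrc1, 1.21 for Ms4a7, 1.17 for Cckbr, 1.12 for Lmo7, 1.05 for Sez6l, 1.02 for Ctss, 0.97 for Hist1h1c, 0.88 for Csf1r, 0.77 for Csf1, 0.76 for Ednrb and 0.67 for Hsd17b7, all of which rose. It was -0.77 for Fkbp5, -0.95 for Pde4c, -1.01 for Lpar5, -1.03 for Olfr920, -1.17 for Zbtb16 and -1.46 for Fam150b, all of which fell. With 1 library left out at a time, Gal, Anxa1, Lmo7 and Sez6l passed in all 12 fits, with a highest adjusted p in limma of 0.0304, 0.0304, 0.0332 and 0.0441. Sprr1a lost its call without naive replicate 1 (0.0509), day 1 replicates 2 (0.0595) and 3 (0.114) or day 3 replicates 1 (0.0974), 2 (0.129) and 3 (0.0982). The call of Nts ended without day 1 replicate 3 (0.0606). For Car3 the adjusted p was above 0.05 without day 1 replicates 1 (0.0937) and 2 (0.109) or day 3 replicates 1 (0.0921), 2 (0.114) and 3 (0.111). Npy lost its call without naive replicate 2 (0.0632), day 1 replicates 2 (0.152) and 3 (0.143), day 3 replicates 1 (0.113), 2 (0.148) and 3 (0.146) or day 7 replicate 3 (0.0533). The call of Mrc1 ended without day 3 replicate 2 (0.0534). For Ms4a7 the adjusted p was above 0.05 without naive replicates 1 (0.0574), 2 (0.0577) and 3 (0.0549), day 1 replicates 1 (0.114) and 3 (0.15), day 3 replicates 2 (0.165) and 3 (0.171) or day 7 replicates 2 (0.0567) and 3 (0.0533). Cckbr lost its call without day 1 replicates 2 (0.0846) and 3 (0.0899) or day 3 replicates 1 (0.0776) and 2 (0.113). The call of Ctss ended without naive replicates 1 (0.0574), 2 (0.0732) and 3 (0.0604), day 1 replicates 1 (0.0937), 2 (0.127) and 3 (0.15), day 3 replicates 1 (0.0869), 2 (0.214) and 3 (0.135) or day 7 replicate 3 (0.0533). For Hist1h1c the adjusted p was above 0.05 without naive replicates 1 (0.062), 2 (0.0577) and 3 (0.0675), day 1 replicates 1 (0.155), 2 (0.148) and 3 (0.114), day 3 replicates 2 (0.221) and 3 (0.19) or day 7 replicates 2 (0.0567) and 3 (0.06). Csf1r lost its call without naive replicates 1 (0.0635), 2 (0.0577) and 3 (0.0675), day 1 replicates 1 (0.147), 2 (0.18) and 3 (0.0938), day 3 replicates 1 (0.12), 2 (0.231) and 3 (0.124) or day 7 replicates 2 (0.0646) and 3 (0.06). The call of Csf1 ended without day 1 replicates 2 (0.0876) and 3 (0.075) or day 3 replicates 1 (0.0898), 2 (0.0792) and 3 (0.0942). For Ednrb the adjusted p was above 0.05 without naive replicate 3 (0.0549), day 1 replicates 2 (0.128) and 3 (0.108) or day 3 replicates 1 (0.0974), 2 (0.115) and 3 (0.131). Hsd17b7 lost its call without naive replicates 1 (0.0547), 2 (0.0577) and 3 (0.0755), day 1 replicates 1 (0.075), 2 (0.154) and 3 (0.176), day 3 replicates 1 (0.168), 2 (0.148) and 3 (0.129) or day 7 replicate 2 (0.0615). The call of Fkbp5 ended without naive replicates 2 (0.0632) and 3 (0.0604), day 1 replicates 1 (0.12), 2 (0.109) and 3 (0.144) or day 3 replicates 1 (0.107), 2 (0.148) and 3 (0.155). For Pde4c the adjusted p was above 0.05 without day 1 replicates 1 (0.0669), 2 (0.109) and 3 (0.0894) or day 3 replicates 2 (0.0909) and 3 (0.111). Lpar5 lost its call without naive replicates 1 (0.0659), 2 (0.0632) and 3 (0.0721), day 1 replicates 1 (0.0937), 2 (0.196) and 3 (0.143), day 3 replicates 1 (0.19) and 2 (0.218) or day 7 replicates 2 (0.0646) and 3 (0.0606). The call of Olfr920 ended without day 1 replicates 1 (0.113) and 2 (0.115) or day 3 replicates 1 (0.0876), 2 (0.0908) and 3 (0.124). For Zbtb16 the adjusted p was above 0.05 without naive replicates 1 (0.0635), 2 (0.0732) and 3 (0.0731), day 1 replicates 1 (0.198), 2 (0.155) and 3 (0.0905), day 3 replicates 2 (0.214) and 3 (0.19) or day 7 replicate 2 (0.0643). Fam150b lost its call without day 1 replicates 1 (0.0609) and 2 (0.0625) or day 3 replicate 2 (0.0534).

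From day 1 to day 7, the log2 fold change was 3.61 for Sprr1a, 2.16 for Nts, 1.82 for Npy, 1.79 for Loxl2, 1.73 for Gal, 1.70 for Ctss, 1.67 for Ms4a7, 1.57 for Car3, 1.42 for Csf1r, 1.31 for Anxa1, 1.23 for Top2a, 1.21 for Mpeg1, 0.97 for Col3a1, 0.86 for Lmo7, 0.82 for Sez6l, 0.81 for Ednrb, 0.75 for St6gal2 and 0.60 for Col1a2, all of which rose. It was -0.73 for Fosl2, -0.81 for Fkbp5, -0.87 for Timp1, -0.96 for Igfbp3, -1 for Olfr920, -1.01 for Bdnf, -1.08 for Tmem79, -1.09 for Pde4c, -1.10 for Adcyap1, -1.10 for Asphd1 and -1.76 for Fam150b, all of which fell. With 1 library left out at a time, Nts, Npy, Loxl2, Gal, Ctss, Ms4a7, Csf1r, Anxa1, Mpeg1, Col3a1, Bdnf, Pde4c, Adcyap1 and Fam150b passed in all 12 fits, with a highest adjusted p in limma of 0.0376, 0.0469, 0.019, 0.0376, 0.0179, 0.0237, 0.019, 0.0246, 0.0207, 0.0214, 0.0448, 0.0368, 0.0499 and 0.0179. Sprr1a lost its call without day 1 replicate 3 (0.075) or day 7 replicates 2 (0.0687) and 3 (0.0546). The call of Car3 ended without naive replicate 3 (0.08), day 1 replicates 1 (0.175) and 2 (0.165), day 3 replicates 1 (0.0826), 2 (0.0777) and 3 (0.0761) or day 7 replicates 2 (0.156) and 3 (0.128). For Top2a the adjusted p was above 0.05 without day 1 replicates 1 (0.108), 2 (0.0669) and 3 (0.111) or day 7 replicates 1 (0.0972), 2 (0.0819) and 3 (0.0606). Lmo7 lost its call without day 1 replicate 3 (0.0529). The call of Sez6l ended without day 1 replicates 2 (0.0713) and 3 (0.075) or day 7 replicates 2 (0.0694) and 3 (0.0588). For Ednrb the adjusted p was above 0.05 without day 1 replicates 2 (0.0529) and 3 (0.0529) or day 7 replicate 2 (0.0602). St6gal2 lost its call without naive replicate 3 (0.0508), day 1 replicates 1 (0.134), 2 (0.0714) and 3 (0.0571) or day 7 replicates 1 (0.071), 2 (0.101) and 3 (0.081). The call of Col1a2 ended without day 1 replicates 1 (0.133) and 3 (0.0877) or day 7 replicates 2 (0.0771) and 3 (0.0906). For Fosl2 the adjusted p was above 0.05 without naive replicate 2 (0.0582), day 1 replicates 1 (0.178), 2 (0.0781) and 3 (0.0811), day 3 replicates 1 (0.0582), 2 (0.0587) and 3 (0.0598) or day 7 replicates 1 (0.0788), 2 (0.0619) and 3 (0.122). Fkbp5 lost its call without day 1 replicates 1 (0.0775) and 3 (0.0842) or day 7 replicates 1 (0.0655) and 2 (0.0783). The call of Timp1 ended without day 1 replicates 1 (0.0508) and 3 (0.0508). For Igfbp3 the adjusted p was above 0.05 without naive replicates 1 (0.0543), 2 (0.0558) and 3 (0.0755), day 1 replicates 1 (0.202) and 3 (0.14), day 3 replicates 1 (0.0708), 2 (0.0591) and 3 (0.0633) or day 7 replicates 1 (0.0843) and 3 (0.14). Olfr920 lost its call without day 1 replicates 1 (0.096) and 2 (0.0714) or day 7 replicates 2 (0.0771) and 3 (0.0861). The call of Tmem79 ended without day 1 replicates 1 (0.0534) and 3 (0.0871). For Asphd1 the adjusted p was above 0.05 without naive replicate 1 (0.0532), day 1 replicates 1 (0.118) and 3 (0.15), day 3 replicates 1 (0.052) and 2 (0.0579) or day 7 replicates 1 (0.0977) and 3 (0.114). Of the genes that passed in all 12 fits, Npy missed the threshold with a pseudocount of 0.1 (0.232), which was chosen after the data had been seen, and Adcyap1 with only the groups compared in the model (0.0957). Mrc1, which the rule did not take between these days, rose by 1.08 (adjusted p = 0.00859 in limma), and its call was not recomputed under other settings.

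The macrophage list had a median log2 fold change of 1.10 from day 1 to day 7 over 20 genes, of which 6 rose (14 adjusted over the list alone). It was the 1 list of 29 that passed between days when the correlation was estimated (adjusted p = 0.0371 with an estimated correlation). Reads of Olfr920, of the olfactory receptor family, and of the histone gene Hist1h1c can be shared with near-identical copies, so their levels are uncertain.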

How the results depend on the processing

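The pseudocounts, array weights, filter at RPKM 5, absence of scaling, length and GC correction and fits without 2 chosen libraries were added after the data had been seen; the other settings were fixed beforehand. Counts of changed genes under RLE or upper-quartile scaling, no scaling, pseudocounts of 0.1 and 1, no robust moderation and without the 2 libraries apart on the second component stayed within 1.5 times those reported. Against 489, 799 and 415 genes at days 1, 3 and 7 from naive, voom on recovered reads gave 1558, 2258 and 939, with 384 at day 3 against day 1, 299 at day 7 against day 1 and 2319 at any time. Array weights gave 1836, 1947, 833, 349, 294 and 2101 in the same order. Of the 489, 799 and 415 genes, 483, 796 and 399 were shared with voom and 489, 799 and 409 with array weights. The length and GC correction gave 836, 1347, 880, 165, 283 and 1247, and 2 genes at day 7 against day 3, where limma called 0 (718 at an unadjusted p under 0.05), voom 0, no filter 4 and only the groups compared 1. With only the groups compared, 256 genes passed at day 7 and 38 at day 7 against day 1. The filter at RPKM 5 gave 47 genes at day 3 against day 1, 5 lists at day 1, 9 at day 3 and 9 at day 7 against day 1. Without naive replicate 1 and day 7 replicate 2, 277 genes passed at day 1, 166 at day 7, 57 at day 7 against day 1 and 405 at any time. A log2 fold change of at least 1 left 152, 248 and 187 genes at days 1, 3 and 7, 40 at day 3 against day 1 and 65 at day 7 against day 1. With an estimated correlation, camera called 1, 6 and 6 lists at days 1, 3 and 7, 0 at day 3 against day 1, 0 at day 7 against day 3 and 1 at day 7 against day 1, where the preset correlation called 13, 8 and 14 in those last 3. At an unadjusted p under 0.05 the estimated correlation gave 5, 0 and 6 lists there, and fry called 3, 0 and 3. A larger required fold lowers a count by construction, and for the other settings the cause was not tested.

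With the replicate block, 31 genes passed at day 3 and 91 at day 7 against day 1. Of these, 30 and 87 were among the 72 and 138. Counts against naive stayed within 1.5 times and list counts did not move. The 18 same-number pairs had deviations correlated at -0.34 to 0.234, all positive between days 3 and 7. Not every library correlated best with its own number, and a shared batch stays open.

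Leaving out 1 library at a time gave 218 to 617 genes at day 1, 449 to 1081 at day 3, 235 to 518 at day 7, 13 to 106 at day 3 against day 1, 0 to 2 at day 7 against day 3, 54 to 120 at day 7 against day 1 and 383 to 903 at any time. Lists called ranged over 5 to 11, 14 to 17, 13 to 19, 10 to 13, 4 to 9 and 6 to 15 in that order of comparisons. Counts moved by over 1.5 times at day 1 without naive replicates 1, 2 and 3 (284, 290 and 248) or day 1 replicate 1 (218), at day 3 without naive replicates 2 and 3 (452 and 449) or day 3 replicates 1 and 2 (515 and 484), and at day 7 without naive replicates 2 and 3 (239 and 235). At day 3 against day 1 they did so without naive replicates 2 and 3 (43 and 41), day 1 replicates 1, 2 and 3 (32, 22 and 17) or day 3 replicates 1, 2 and 3 (23, 13 and 25), at day 7 against day 1 without day 1 replicates 1, 2 and 3 (66, 82 and 54) or day 7 replicates 2 and 3 (62 and 70), and at day 7 against day 3 without day 1 replicate 1 (2). At any time they did so without naive replicates 1, 2 and 3 (450, 383 and 388), and for lists without naive replicate 2 at day 1 (5) and without day 7 replicate 3 at day 7 against day 3 (4) and day 7 against day 1 (6). A tally covered the genes taken by rank or fixed beforehand and the list members named in the text, not the other list members. Under the other settings 4386 of its values kept direction and side of the threshold, 241 lost and 138 gained a call and 0 reversed. Leaving out 1 library kept 3410, ended 419, added 29 and reversed 0. In data simulated for days 1, 3 and 7 against naive, 22.4, 13.4 and 23.9% of genes changed 1.5-fold were called. The shares were 61.2, 56.7 and 55.2% for those changed 2-fold and 95.5, 77.3 and 80.3% for those changed 4-fold. Smaller changes could thus not be excluded at this depth and number of libraries. Each simulated comparison changed 67, 67 and 66 genes at these folds and drew genes independently, so the shares may differ in the real data. DESeq2, svaseq and a filter at 50 reads were not run.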

Other observations

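The tests of neuronal share, of single libraries and of muscle transcripts were chosen only after the result was seen. The predictions for the splits and for length and GC were written before, although the length and GC correction itself was added after the data had been seen. Several lists of cells that surround the neurons had few called members. Among 17 satellite glia genes, 1 rose and 1 fell at day 1 (1 and 1 adjusted over the list alone; median -0.07, adjusted p = 0.465 in camera), 1 rose at day 3 (1 over the list alone; 0.08, 0.767), and at day 7 limma called 0 (1 at an unadjusted p under 0.05, 1 by voom; 0.08, 0.651). Ednrb, an endothelin receptor, fell by 0.66 at day 1, a call lost without naive replicates 2 (0.0817) and 3 (0.0706) and day 1 replicates 2 (0.0699) and 3 (0.0565). Glul, which makes glutamine from glutamate, rose at day 3 from 17.0 ± 2.47 to 29.4 ± 1.74 RPKM (SD, n = 3; log2 fold change 0.78, SE 0.16, adjusted p = 0.0104 in limma), a call lost without naive replicate 3 (0.0653). Of 19 myelin genes, 1 fell at day 1 (2 adjusted over the list alone), and the medians were -0.09, -0.04 and -0.03 at days 1, 3 and 7 (adjusted p = 0.316, 0.817 and 0.748). Of 11 genes of repair Schwann cells, 1, 2 and 1 rose (2, 3 and 2 higher and 1, 0 and 0 lower adjusted over the list alone; medians -0.06, 0.02 and 0.00, adjusted p = 0.612, 0.225 and 0.509), and at day 1 the mean was 0.10. Bdnf, a neurotrophin of that list that sensory neurons also make, rose at day 1 from 3.93 ± 0.679 to 10.1 ± 1.06 RPKM (1.27, SE 0.16, adjusted p = 0.000431 in limma) and passed in all 12 fits that left out 1 library.

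Of 10 replication histone genes 1 rose at each day (2, 1 and 2 adjusted over the list alone; medians -0.10, 0.25 and 0.13, adjusted p = 0.531, 0.0683 and 0.0805), and at day 1 the mean was 0.11. Hist1h1c, a linker histone, rose at day 3 by 1.67 (SE 0.19, adjusted p = 0.000109 in limma), with the copies of this family making its level uncertain. Of 20 glucocorticoid and circadian genes 3, 1 and 1 rose (6, 1 and 1 higher and 1, 0 and 0 lower adjusted over the list alone; medians 0.15, -0.01 and 0.08, adjusted p = 0.0703, 0.817 and 0.856), and at day 3 the mean was 0.12. Cdkn1a, a cell cycle inhibitor of that list, rose at day 3 from 5.87 ± 0.717 to 19.7 ± 3.04 RPKM (1.66, SE 0.21, adjusted p = 0.000242 in limma). That list was lower at day 7 than at day 1 (median -0.15, adjusted p = 0.0384, but adjusted p = 0.246 with an estimated correlation), a call lost without day 1 replicates 1 (0.0954) and 3 (0.0966) and day 7 replicates 1 (0.142) and 2 (0.0931), with no scaling (0.0506), after the length and GC correction (0.0814), without the 2 libraries with muscle transcripts (0.0796) and without the 2 apart on component 2 (0.127). Of 5 adipocyte genes 0, 1 and 1 rose (0, 1 and 1 over the list alone; medians -0.07, -0.23 and -0.06 and means -0.10, 0.26 and 0.28, adjusted p = 0.486, 0.937 and 0.651). The riser was Car3, an enzyme also of muscle, which went from 2.30 ± 0.936 to 13.9 ± 1.34 RPKM at day 3 (2.42, SE 0.33, adjusted p = 0.000826 in limma). Of 6 central glia genes 1, 1 and 0 rose (1, 1 and 0 higher and 0, 0 and 1 lower over the list alone; medians -0.23, -0.10 and 0.12, adjusted p = 0.465, 0.587 and 0.988).

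Limma called 0 of 19 vessel genes (medians 0.01, -0.02 and 0.04; adjusted p = 0.886, 0.832 and 0.78; at day 7 the mean was -0.02), 0 of 7 muscle genes (-0.65, -0.91 and -0.27; 0.341, 0.0856 and 0.3), 0 of 72 respiratory chain genes (-0.05, 0.07 and -0.07; 0.465, 0.471 and 0.188) and 0 of 9 neutrophil genes (-0.35, 0.30 and 0.32; 0.286, 0.429 and 0.296) at days 1, 3 and 7 from naive, and also 0 adjusted over each list alone. At an unadjusted p under 0.05 these were 3, 0 and 1 vessel genes, 0, 1 and 1 muscle genes, 0, 1 and 5 respiratory chain genes and 0, 0 and 0 neutrophil genes, and voom called 1, 0 and 0 vessel genes, 0, 3 and 0 respiratory chain genes and 0 of the others. The lymphocyte list with 1 and the erythrocyte list with 3 tested members were not tested. The neutrophil list was higher at day 3 than at day 1 (median 0.65, adjusted p = 0.00491, but adjusted p = 0.462 with an estimated correlation), a call lost without day 1 replicate 3 (0.0714) and day 3 replicate 3 (0.425), and at day 7 than at day 1 (0.86, 0.00845, but adjusted p = 0.406 with an estimated correlation), lost without day 7 replicate 3 (0.0777) and with no expression filter (0.0978). The respiratory chain list was higher at day 3 than at day 1 (median 0.12, adjusted p = 0.0482, but adjusted p = 0.783 with an estimated correlation), lost without naive replicate 2 (0.053), day 1 replicates 1 (0.242) and 2 (0.871) and day 3 replicates 2 (0.95) and 3 (0.114). That call also ended with RLE scaling (0.0515), no expression filter (0.0888), a filter at RPKM 5 (0.0563), no scaling (0.135) and the length and GC correction (0.309). It was lower at day 7 than at day 3 (median -0.14, adjusted p = 0.0021, but adjusted p = 0.803 with an estimated correlation), lost without day 3 replicate 2 (0.53), and without day 7 replicate 1 the median was 0.08 (0.186). It was also lost with voom (0.302), with array weights (0.768) and after the length and GC correction (0.0724), and without the 2 libraries apart on component 2 the median was 0.07 (0.148).

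The lower potassium channel and synaptic lists at day 3 may reflect lower transcript levels in neurons or less neuronal RNA. The 54 channel and synaptic genes had a mean log2 fold change of -0.38 and a median of -0.42, against 0.01 and -0.18 for 19 general neuron markers, a difference of means of -0.39 (permutation p = 0.00025, 100000 resamples, across genes, which are not independent replicates). A lower share of neuronal RNA alone would lower both alike. However, the 2 lists were picked because they lay lower. Of the 19 markers, 8 had an unadjusted p under 0.05 in limma at day 3, so they are not a fixed reference. The comparison therefore cannot decide whether the neuronal share fell. After the length and GC correction the median of 55 genes went from -0.41 to -0.40, a ratio of 0.98 (95% interval 0.88 to 1.23 over 2000 resamples), which argues against such a bias. A change within neurons after injury remains a hypothesis, and other causes were not tested.

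The higher ribosomal protein list at day 3 could come from single libraries or from a length or GC trend. The list mean ranged over 0.54 within day 3 and 0.48 within naive, while the groups differed by 0.35. Values per library were 0.29, -0.19 and -0.11 in naive replicates 1, 2 and 3 and 0.03, 0.58 and 0.43 at day 3, so a shift of single libraries has the size it needs. After the length and GC correction the median of 80 genes went from 0.31 to 0.19, a ratio of 0.61 (95% interval 0.56 to 0.68), so such a trend could account for part of it and the rest stays open. An effect of injury stays open and untested.

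Muscle transcripts were high in naive replicate 1 and day 7 replicate 2, and muscle tissue in the dissected sample is a candidate source. Of 13 listed muscle genes not used to find the pattern, 11 had their 2 highest libraries there, all but Pvalb and Casq1, and Ttn was at 7.40 and 5.49 RPKM against at most 1.22 elsewhere. Among the genes that led to it, Myh4 was at 9.75 and 10.25 RPKM against at most 2.59 and Acta1 at 4.44 and 3.35, but Ckm, abundant in muscle, was at 1.13 and 0.40 and reached 0.98 in day 1 replicate 3. Of the 17 listed genes 10 had a mean of at least 1 RPKM over the 3 naive libraries, but 4 without naive replicate 1, and 1 stands in another list. No biological explanation was tested.

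For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other split called 489 and 0 genes at day 1, 799 and 0 at day 3, 415 and 0 at day 7, 72 and 0 at day 3 against day 1, 0 and 1 at day 7 against day 3 and 138 and 1 at day 7 against day 1. For lists the values were 8 and 12, 14 and 14, 15 and 16, 13 and 9, 8 and 10 and 14 and 10. For genes only the real split gave a count as large, except at day 7 against day 3. There a real count of 0 fixed it at 10 splits in advance. Other splits mix groups, so real differences widen their spread and low counts there are no neutral reference. For lists a count as large came from 4, 2, 2, 1, 6 and 1 splits. For genes that differed at any time, 1 of 100 splits of the 12 libraries, the real one, gave a count as large (679), a share under 0.05. The highest other split gave 664, so the lead of the real grouping was narrow. This share does not bear on any single comparison between groups.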
